A study of Mus musculus with 2 samples.

How the data were processed

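Pancreatic islets were profiled by droplet single-cell RNA sequencing (10x Genomics 3' chemistry, v3.1) in 2 groups of mice. The control sample is titled wild-type, while its genotype label gives Lepr-lp/lp. It was taken here as a control without Cre that carries these alleles, which the labels do not settle. The Lepr KO group is labelled with the same alleles and Ubc-CreERT2, a Cre recombinase that tamoxifen activates. Both groups received tamoxifen (0.1 mg per g body weight), and islets were isolated on day 9 after its start. Mice were of the B6.129 strain and 8 to 10 weeks old. Each group is 1 library made from islets pooled from 4 mice, with a targeted recovery of 10000 cells. The pool hides the mice, so each group is 1 sample with no replicate. No test was possible, and no p-value or standard error is given. Differences between the libraries may be differences between groups or between single preparations. As labelled, only the Lepr KO group carries Ubc-CreERT2, so effects of active Cre cannot be separated from those of Lepr loss.

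The deposited matrices hold whole-number UMI counts (unique molecular identifiers, which count molecules rather than reads) per gene and barcode, with no normalization. Per the labels they were made with Cell Ranger 3.1 on mouse genome build mm9, while the file headers name version 5.0.1. The gene list holds 32285 Ensembl gene IDs, 32158 of them (99.6%) in the reference annotation used here. Because the build could not be settled, no coordinates are given. The deposited feature lists hold other information, the gene ID and symbol of each matrix line, and no measurement. The deposited barcode lists hold 6794880 barcodes each and do not name the matrix columns, so they were not used. The matrices hold 14941 barcodes for the control library and 16365 for the Lepr KO library. Their totals are 162029296 and 237450264 UMIs. Every barcode in them has at least 500 UMIs, so barcodes below that were left out before deposit.

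Cells were chosen by filters fixed before the data were examined. A test of each barcode against free RNA had been planned, but it needs barcodes with at most 100 UMIs, which the matrices lack. The planned fallback was used: at least 1000 UMIs, at least 500 detected genes, and at most 15% of UMIs from mitochondrially encoded genes. The highest Scrublet doublet scores in each library were then removed at 0.8% per 1000 barcodes, which took out 535 and 737 barcodes. This left 7645 control cells and 8860 Lepr KO cells, with medians of 13901 and 21999 UMIs per cell.

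Cells of both libraries were clustered together without batch integration, on 2000 variable genes without the cell cycle lists, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1. Clusters were named from fixed marker lists. The thresholds of the naming were set after seeing the clusters. A marker counted when it reached 50 CPM and 25% of its level in the highest cluster, and a name needed at least 3 such markers. A cluster stayed unnamed when its 10 leading genes held more markers of another class, or when a hormone gene foreign to its class reached 25% of its highest cluster. For beta-like clusters the foreign hormone genes were Gcg, Sst and Ppy. Classes with at least 100 cells in each library were compared: beta-like, alpha-like, delta-like, gamma-like, endothelial-like and macrophage-like. Mural-like cells, 97 and 195, were not compared further. With 1 library per group, a cluster made mostly of 1 library may be that library and not a cell state.

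For each class, UMIs were summed over the cells of a library, since cells are not replicates. Levels are UMIs out of every 1000000 of the class total, called CPM (counts scaled to that total), with a median-ratio factor between the libraries. Log2 ratios are Lepr KO over control with 1 CPM added to both, while folds are ratios of CPM with nothing added. The interval of a fold is the exact conditional binomial interval (95%), that of a share of cells the exact Clopper-Pearson interval (95%), and that of a UMI sum the exact Poisson interval. All cover counting error only and leave out differences between mice, dissections and library preparations. Genes at least 2-fold apart were counted among those with at least 20 CPM in the higher library, as a description of size. All counts of genes at 2-fold or 1.5-fold use the log2 ratios with 1 CPM added. A gene of low level can therefore fall short of a limit that its fold passes.

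The rule for named genes was fixed before the data were examined. In beta-like cells it took the 12 genes with the largest log2 ratio in each direction, and in other classes the 6 largest. They needed at least 50 CPM and 100 UMIs in the higher library, free RNA of at most 20% of their level, the same direction under every scaling and after free RNA was subtracted, and no mitochondrial origin. From each list that stood apart, the 2 members with the largest ratio in each direction were taken. Lepr, Ins1, Ins2, Iapp, Gcg, Sst, Mki67, Top2a, Pdx1, Mafa, Ucn3, Slc2a2, Gck, Tph1, Tph2, Aldh1a3, Cdkn1a, Ccnd2 and Xist were always included. The profile of free RNA, chosen after seeing the files, was the sum of barcodes under 500 genes and within the mitochondrial limit (2458 control and 3353 Lepr KO barcodes). Some of these barcodes may hold damaged cells. Its share of the UMIs of beta-like cells was estimated from hormones of other cell types at 15.2% in the control and 18.8% in the Lepr KO library. Erythroid markers stood at 8900 CPM in the control profile but 0.749 in control beta-like cells, and acinar markers at 28072 and 114. A share of 15.2% would put both far higher in these cells, so the profile is not free RNA alone. The free RNA values below, and results after its subtraction, are therefore rough and may be too high.

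Fixed gene lists covered hormone secretion, beta cell identity, stress responses, the cell cycle, metabolism, growth signals, immunity and matrix. Each list is summarised by the median log2 ratio of its members with at least 20 UMIs over both libraries. It was placed among 10000 random lists of the same size, matched on expression over 25 bins. A list is said to stand apart at or below percentile 2.5 or at or above 97.5. This percentile describes the 2 libraries and is not a test of the genotype. Members are counted as higher or lower at 1.5-fold on the log2 ratio with 1 CPM added, a limit set after seeing the data.

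A cell was counted as cycling when at least 3 of the 22 genes of a fixed cycling core list had a UMI. For this, each beta-like cell was thinned to 12833 UMIs, the 10th percentile of beta-like cells, and shallower cells were left out (556 control and 423 Lepr KO). Thinning to 2000 UMIs, added after seeing the data, allowed a comparison across classes.

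Alternatives changed 1 choice at a time: a minimum of 2000 UMIs per cell, mitochondrial limits of 10% and 25%, no doublet removal, each library clustered alone, clustering at resolution 2, CPM without further scaling or without hormone genes, the same weight for each cell, subtraction of free RNA, pseudocounts of 0.1 and 5, no filter on low counts, a filter of 50 CPM, thinning of all cells to 1 depth, 2 or 5 cycling genes, and no thinning. Leaving out cells with a UMI of a cycling core gene or of an acinar marker was added after seeing the data. The calculations were tested on simulated data with known folds. In a simulation of beta-like cells, all 67 genes set 2-fold apart had the right direction, and with no true difference 0 of 2766 genes reached 2-fold. Some lists stood apart with no true difference: 2 of 34 in beta-like, 2 of 32 in alpha-like and 2 of 29 in macrophage-like cells. In macrophage-like cells, the smallest class, 496 of 4923 genes reached 2-fold by counting error alone, so no such count is given for that class. Simulation covers counting error only. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.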

Results

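The series compared pancreatic islets of control mice with islets of mice in which Lepr, the receptor for the satiety hormone leptin, was targeted for deletion in adults. Its stated question was how islet cells differ while beta cells expand in early obesity. Tamoxifen was given to both groups, and islets were taken on day 9. There was 1 library per group, each pooled from 4 mice, so no value below has a replicate and no difference was tested. The control library held 162029296 UMIs and the Lepr KO library 237450264. After filtering, 7645 control cells and 8860 Lepr KO cells remained, with medians of 2585 and 2828 detected genes. Every interval covers counting error at 95% and says nothing about variation between mice.

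Beta-like cells made up a larger share of the Lepr KO library, and alpha-like and gamma-like cells a smaller one. Beta-like cells, which make insulin, were 50.3% of control cells (3843 cells, interval 49.1 to 51.4%) and 67.1% of Lepr KO cells (5944 cells, interval 66.1 to 68.1%). Glucagon-producing alpha-like cells were 21.0% of the control library (20.1 to 22.0%) and 13.4% of the Lepr KO library (12.7 to 14.1%). Gamma-like cells, which make pancreatic polypeptide, were 4.97% (4.49 to 5.48%) and 1.83% (1.56 to 2.13%). Somatostatin-producing delta-like cells were nearer to each other, at 6.91% and 5.99%.

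Of the 4 endocrine classes alone, beta-like cells were 60.4% in the control and 76.0% in the Lepr KO library. Endothelial-like cells were 5.10% and 5.69%, and their intervals overlapped. Macrophage-like cells were 2.09% and 1.13%, and mural-like cells 1.27% and 2.20%. Unnamed clusters held 8.35% of control cells and 2.67% of Lepr KO cells. Of these, 3 clusters led by genes of the digestive enzyme-producing acinar cells held 400 control cells (5.23%) and 2 Lepr KO cells (0.0226%). By their markers, clusters 16 and 21 (250 and 116 control cells) were closest to beta cells. Cluster 24 (34 control and 2 Lepr KO cells) was closest to acinar cells. Adding all 3 clusters, cluster 24 included, to the beta-like class brings its control share to 55.5% and leaves 67.1% in the Lepr KO library. Shares of dissociated cells also depend on which cells survive. Median depth over all cells was higher in the Lepr KO library, 21999 against 13901 UMIs, but this median also depends on the shares themselves. Within classes, the Lepr KO median was 1.13 times the control median in beta-like cells and 1.19 times in mural-like cells. In the other named classes it was lower than in the control.

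**Figure D1:**
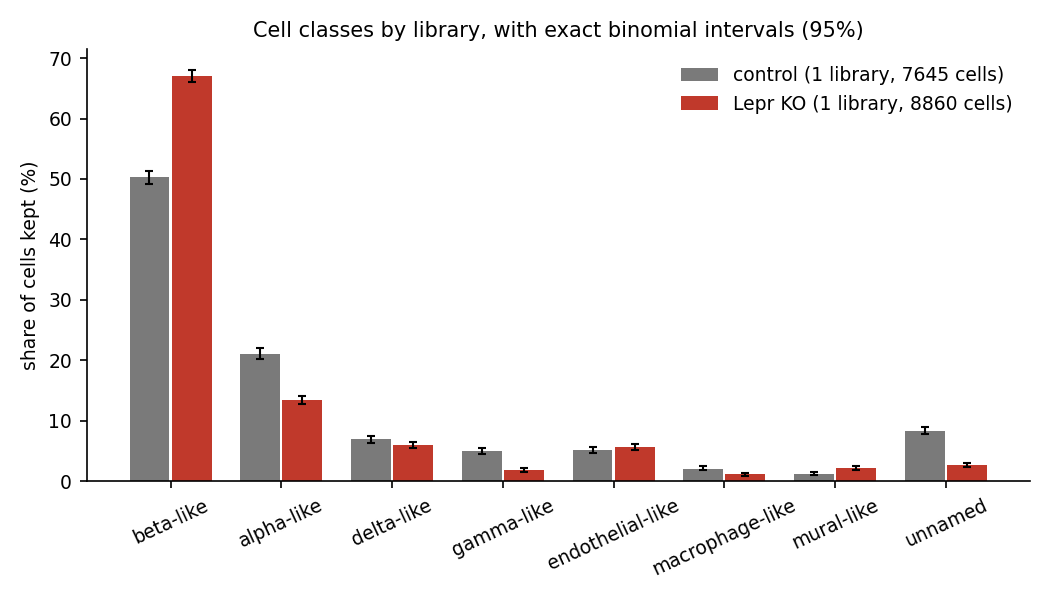
Share of the cells kept (%, y axis) in each cell class (x axis) for the control and Lepr KO libraries, with exact binomial intervals (95%) as error bars. Beta-like cells were 50.3% of the control and 67.1% of the Lepr KO library, while alpha-like cells were 21.0% and 13.4%.

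Cycling beta-like cells were 18.3 times as frequent in the Lepr KO library as in the control library. With each cell thinned to 12833 UMIs, 19 of 3287 control beta-like cells (0.578%, interval 0.348 to 0.901%) carried UMIs of at least 3 cycling core genes. In the Lepr KO library 583 of 5521 did (10.6%, interval 9.76 to 11.4%). The ratio of the shares had a counting interval of 11.6 to 30.6. Transcripts of Mki67 (ENSMUSG00000031004), which marks dividing cells, numbered 177 in control and 6277 in Lepr KO beta-like cells, a 19.9-fold higher level in the Lepr KO library (17.2 to 23.3). Top2a (ENSMUSG00000020914), which untangles DNA strands, was 15.9-fold higher (14.0 to 18.2).

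All 3 cell cycle lists stood apart from random lists of similar expression in beta-like cells. All 31 genes of G2 and mitosis were at least 1.5-fold higher in the Lepr KO library, with a median log2 ratio of 2.66. Of the 25 DNA replication and S phase genes 23 were, with a median of 1.25, among them Hells (10.6-fold) and the replication licensing gene Mcm5 (13.1-fold). Both are low, so their log2 ratios with 1 CPM added were 2.12 and 2.05, and 0.95 and 0.84 with a pseudocount of 5. The cycling core list had a median of 2.97. Among cyclins and cell cycle inhibitors 5 genes were higher and 1 lower of 18, with a median of 0.17, which no longer stood apart with free RNA subtracted or without cells that had a cycling UMI. Foxm1, a low transcript of a mitotic transcription factor, was 7.60-fold higher, with a log2 ratio of 1.53, and of 0.079 without cells that had a cycling UMI. The inhibitor Cdkn1a was 1.95-fold higher (1.87 to 2.05). The inhibitor Cdkn1b was 1.26-fold lower. Cdkn1c was 2.52-fold lower on 174 and 123 UMIs, with a log2 ratio of -0.69, and of -0.24 with a pseudocount of 5. Ccnd2, a cyclin of beta cells, stood at 523 and 483 CPM (UMIs out of every 1000000 of its class and library).

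The difference in cycling was not seen at this size in other classes. At 2000 UMIs per cell, the cycling share was 0.286% of control and 6.93% of Lepr KO beta-like cells, whose median depths were 24403 and 27682 UMIs before thinning. Alpha-like cells, with median depths of 7080 and 6828 UMIs, gave 0.126% (2 cells) and 0.340% (4 cells). For all other compared classes together the shares were 0.609% and 0.663%, a ratio of 1.09 (0.519 to 2.26). Gamma-like cells gave 0 of 376 control cells, with an upper limit of 0.976%, and 0 of 158 Lepr KO cells, with an upper limit of 2.31%. Without thinning, 0.572% of control and 12.5% of Lepr KO beta-like cells were counted as cycling. The other compared classes together then gave 0.815% and 1.21%, a ratio of 1.48 (0.842 to 2.63). Among gamma-like cells these were 0 of 380 control and 2 of 162 Lepr KO cells.

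**Figure D2:**
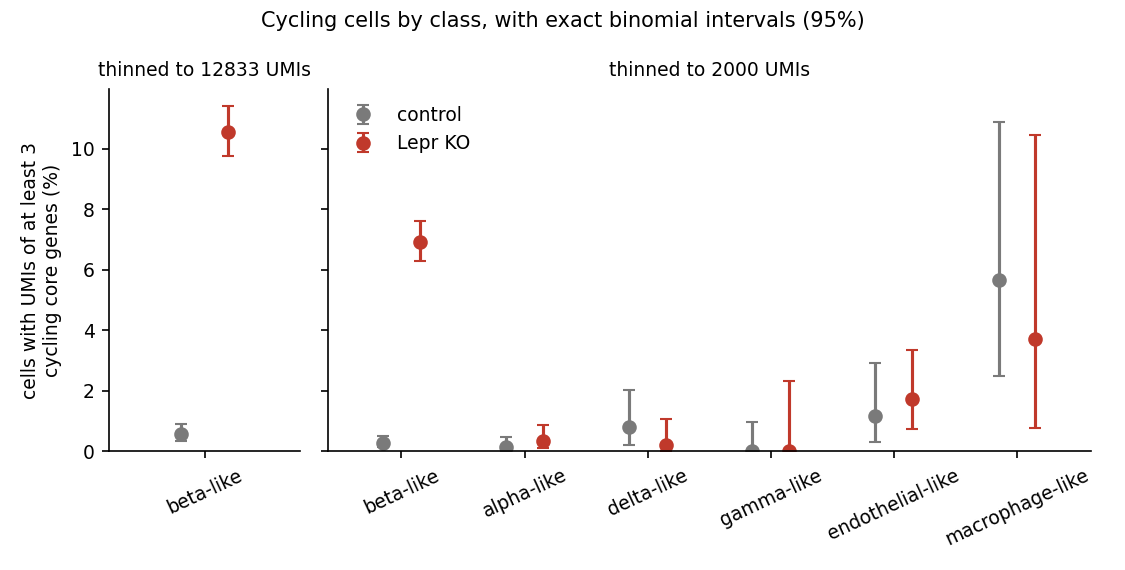
Share of cells with UMIs of at least 3 cycling core genes (%, y axis) by cell class (x axis) and library, as points with exact binomial intervals (95%). The left panel has beta-like cells thinned to 12833 UMIs, at 0.578% and 10.6%. The right panel has all compared classes thinned to 2000 UMIs, where beta-like cells stand at 0.286% and 6.93%.

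Beta-like cells of the Lepr KO library held more RNA for protein entry into and folding in the endoplasmic reticulum, and less RNA for metallothioneins and several genes of mature beta cells. Of 2998 genes with at least 20 CPM, 54 were at least 2-fold higher and 37 at least 2-fold lower in the Lepr KO library. Scaling without the hormone genes gave 124 and 116, and over all alternatives the counts ran from 23 to 289 and from 17 to 116. Different clusters held most of these cells. Clusters 1, 8 and 12 held 3628 of the 3843 control beta-like cells (94.4%). Clusters 2, 4, 5, 9, 17 and 18 held 5487 of the 5944 Lepr KO beta-like cells (92.3%). The libraries were not integrated, so cell state and library cannot be separated here.

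The insulin genes themselves were close. Ins1 was 1.04 times as high in the Lepr KO library, and Ins2 was 1.09-fold lower. Iapp, which encodes the co-secreted amylin, was 1.48-fold higher. The secretory granule list had a median log2 ratio of 0.29, with 6 of its 22 genes at least 1.5-fold higher and 2 lower. It no longer stood apart without cells that had an acinar UMI (0.27). Vgf, a granule protein, was 7.65-fold higher (log2 ratio 2.39, or 1.45 with a pseudocount of 5) and Ptprn 2.00-fold higher. The zinc transporter gene Slc30a8 was 1.52-fold lower and Scgn 1.61-fold lower.

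The list of chaperones and the unfolded protein response of the endoplasmic reticulum had a median log2 ratio of 0.70. Of its 23 genes, 12 were at least 1.5-fold higher in the Lepr KO library and none was 1.5-fold lower. Creld2 was 3.61-fold higher (3.49 to 3.73), the cochaperone Sdf2l1 2.98-fold (2.92 to 3.03) and the signal peptidase subunit Sec11c 2.56-fold (2.52 to 2.59). Canx and Xbp1 were slightly lower, at log2 ratios of -0.20 and -0.16. Outside the list, the folding gene Fkbp11 (ENSMUSG00000003355) stood at 86.0 CPM in the control and 411 in the Lepr KO library, 4.78-fold higher. Ssr4, a subunit of the translocon-associated complex, was 3.32-fold higher. At 2000 UMIs per cell, Fkbp11 had a UMI in 13.5% of control and 50.9% of Lepr KO beta-like cells, against 4.67% and 7.48% of alpha-like cells. The share was also higher in Lepr KO cells of the delta-like (14.0% and 17.5%), gamma-like (10.4% and 17.1%) and endothelial-like classes (0.287% and 6.42%). Macrophage-like cells gave 0.709% and 2.47%, on 1 and 2 cells.

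The ATF4 and integrated stress response list had a median of 0.39, with 8 of 21 genes higher and 2 lower. The serine synthesis genes Psat1 and Phgdh were 3.27-fold and 2.32-fold higher (Psat1 log2 ratio 1.30, or 0.68 with a pseudocount of 5), while Ddit4 was 2.27-fold lower. Atf3 was 2.54-fold lower, but free RNA came to 179% of its level, and its direction turned when free RNA was subtracted (log2 ratio 0.03).

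The list of beta cell identity and glucose sensing was lower in the Lepr KO library, with a median log2 ratio of -0.44. None of its 19 genes was at least 1.5-fold higher and 5 were lower. The list also stood apart as lower in gamma-like cells, with a median of -0.36, which was 0.088 with free RNA subtracted. Slc2a2, the glucose transporter of mouse beta cells, was 2.11-fold lower (2.07 to 2.14). The ion channel gene Trpm5 was 4.13-fold lower, and Glp1r, the receptor for the gut hormone GLP-1, was 2.19-fold lower. Mafa, a transcription factor of mature beta cells, was 1.75-fold lower, Ucn3 1.44-fold and Gck, the glucokinase gene, 1.46-fold. Pdx1 (log2 ratio 0.12) and G6pc2 (0.19) were slightly higher.

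Genes of immature or dedifferentiated beta cells had a median of 0.26, with 4 of 14 higher and 1 lower. Mafb, at a log2 ratio of -0.53 with 1 CPM added, fell just short of being counted as lower. The list was not higher in this class alone, with medians of 0.41 in delta-like, 0.34 in gamma-like and 0.48 in macrophage-like cells, the last reversed under 2 alternatives. Gc, a vitamin D-binding protein, was 9.02-fold higher and had a UMI in 2.19% of control and 17.5% of Lepr KO beta-like cells. Alpha-like cells, which also express it, had a UMI in 32.6% and 37.0%. Aldh1a3 was low in both libraries, with 11 and 357 UMIs, an 18.2-fold difference (10.1 to 36.9) and a log2 ratio of 1.42, or 0.44 with a pseudocount of 5. Sox4 was 3.90-fold lower in the Lepr KO library. This list no longer stood apart without doublet removal (median 0.11), with each library clustered alone (0.01), at a mitochondrial limit of 25% (0.11), or without cells that had an acinar UMI (0.13).

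The largest ratio among genes with at least 50 CPM was that of Dapl1, at 35.1 and 484 CPM (13.8-fold). Free RNA was estimated at 18.9% of its level, close to the limit of 20% set for named genes. Other genes higher in the Lepr KO library were Stmn1, a tubulin-binding protein (9.73-fold), Tent5a, a poly(A) polymerase (5.97-fold), Nucb2, the nesfatin precursor (3.65-fold), Pde10a (2.82-fold) and Tubb5 (2.63-fold). Over the alternatives, the log2 ratio of Stmn1 fell from 3.15 to as low as 1.01, and that of Tubb5 from 1.37 to 0.40. Among genes with at least 50 CPM, metallothionein genes showed the largest ratios in the other direction. Mt1 (ENSMUSG00000031765) stood at 787 CPM in the control and 120 in the Lepr KO library, 6.54-fold lower (6.44 to 6.63). Mt2 was 8.52-fold lower. Camk2n1 (2.76-fold), Gadd45g (2.57-fold), Glul (2.27-fold), Dennd4c (2.25-fold) and Ttc28 (2.23-fold) were also lower.

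**Figure D3:**
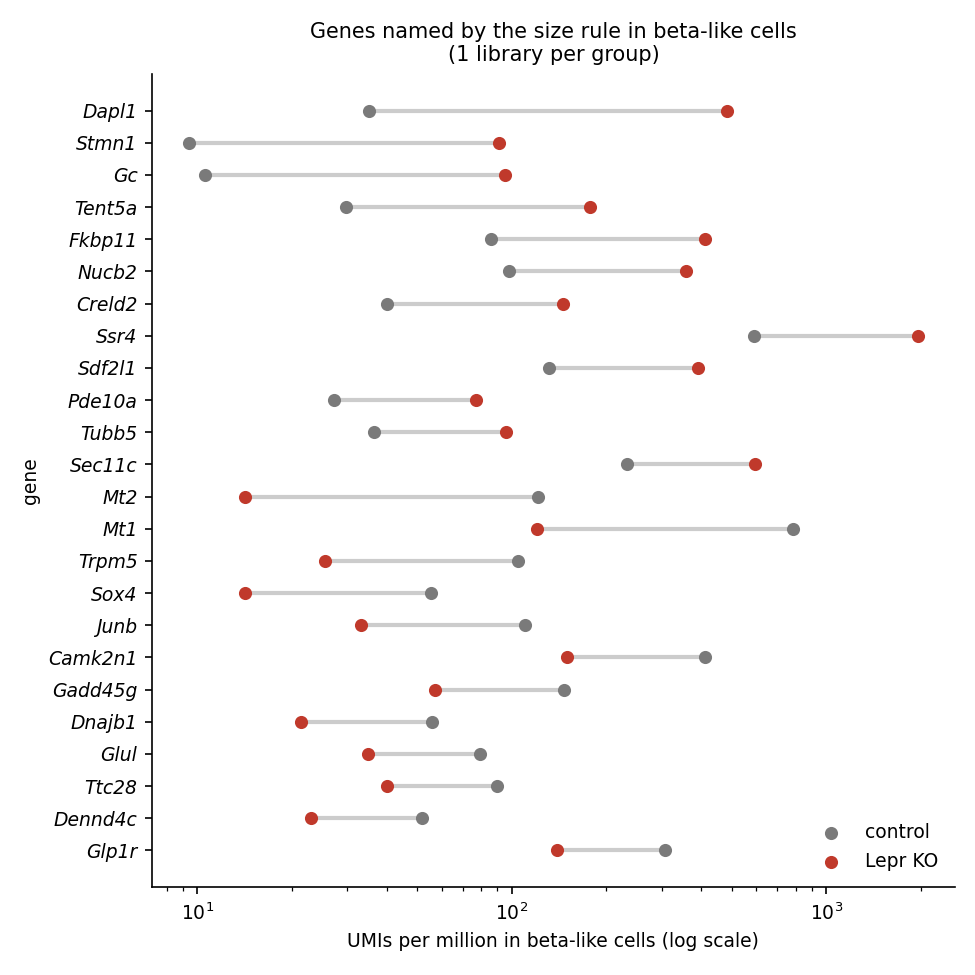
Levels of the genes named by the size rule in beta-like cells (y axis) in CPM on a log scale (x axis), with 1 point per library and a line joining them. The upper 12 genes were higher in the Lepr KO library, from Dapl1 (35.1 and 484) to Sec11c (232 and 593). The lower 12 were lower in it, among them Mt1 (787 and 120).

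Immediate early and heat shock genes were lower in beta-like cells of the Lepr KO library, but not in this class alone. The heat shock list stood apart as lower in every compared class, and the immediate early list in all but endothelial-like cells. Among immediate early and dissociation genes in beta-like cells, 11 of 21 were at least 1.5-fold lower and 2 were higher, with a median of -0.76. Junb was 3.32-fold lower and Egr1 2.02-fold lower, while Nr4a2 and Nr4a1 were 2.15-fold and 1.79-fold higher. The heat shock list had a median of -0.55 and 5 of 13 genes at least 1.5-fold lower, with Hspa1b 5.98-fold, Hspa1a 5.01-fold and Dnajb1 2.61-fold lower. Mitochondrially encoded transcripts had a median of -0.46, with mt-Co2 and mt-Cytb 1.45-fold and 1.44-fold lower.

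Interferon response genes in beta-like cells had a median of 0.30, with 7 of 20 higher and none lower. Rsad2 was higher on 25 and 845 UMIs, a fold of 12.8 to 29.5 by its counting interval, and Bst2 4.64-fold higher. Free RNA was estimated at 62.6% and 39.5% of their levels. The share of beta-like cells with UMIs of at least 5 interferon genes was taken at 12833 UMIs per cell. It was 0.243% (0.105 to 0.479%) in the control and 1.59% (1.28 to 1.96%) in the Lepr KO library. Cluster 18, led by Rsad2, Ifit1 and Cxcl10, held 6 control and 133 Lepr KO cells. MHC class I presentation genes had a median of -0.33, with Psmb9 1.94-fold lower, and no longer stood apart without acinar-UMI cells (-0.34). Hypoxia genes had a median of -0.34 and growth factor ligands one of -0.20, with Ankrd37 1.89-fold and Wnt4 1.51-fold lower. Hypoxia no longer stood apart with a pseudocount of 5 (-0.17) or no filter on low counts (-0.087). Growth factor ligands did not with free RNA subtracted (-0.10), no filter (-0.011) or acinar-UMI cells left out (-0.19). Cholesterol synthesis genes had a median of 0.13, with Pmvk 1.57-fold higher and Hmgcr 1.25-fold lower, and did not stand apart with free RNA subtracted (0.086).

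The other 17 lists did not stand apart in beta-like cells. Of these, carbohydrate response came to stand apart as lower in 5 of 17 alternatives and extracellular matrix in 6. Their medians lay between -0.23 for extracellular matrix and 0.27 for cytosolic ribosomal proteins. They included glycolysis (-0.06), the TCA cycle and anaplerosis (0.03), the nuclear-encoded respiratory chain (0.17), fatty acid synthesis (-0.17), fatty acid oxidation (-0.19), carbohydrate response (-0.21) and p53 targets (0.04). Antioxidant genes (-0.07), ribosome biogenesis (0.06), lysosome and autophagy (-0.06), inflammatory macrophage (-0.20), resident macrophage (-0.01) and endothelial activation (0.00) did not stand apart either. Genes normally kept low in beta cells had a median of -0.11. Lactogenic and serotonin genes, which mark beta cell expansion in pregnancy, had a median of -0.03. Tph1, which starts serotonin synthesis, had 1 UMI in the control and 2 in the Lepr KO library, and Tph2 had 21 and 40, too few to show a difference.

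**Figure D4:**
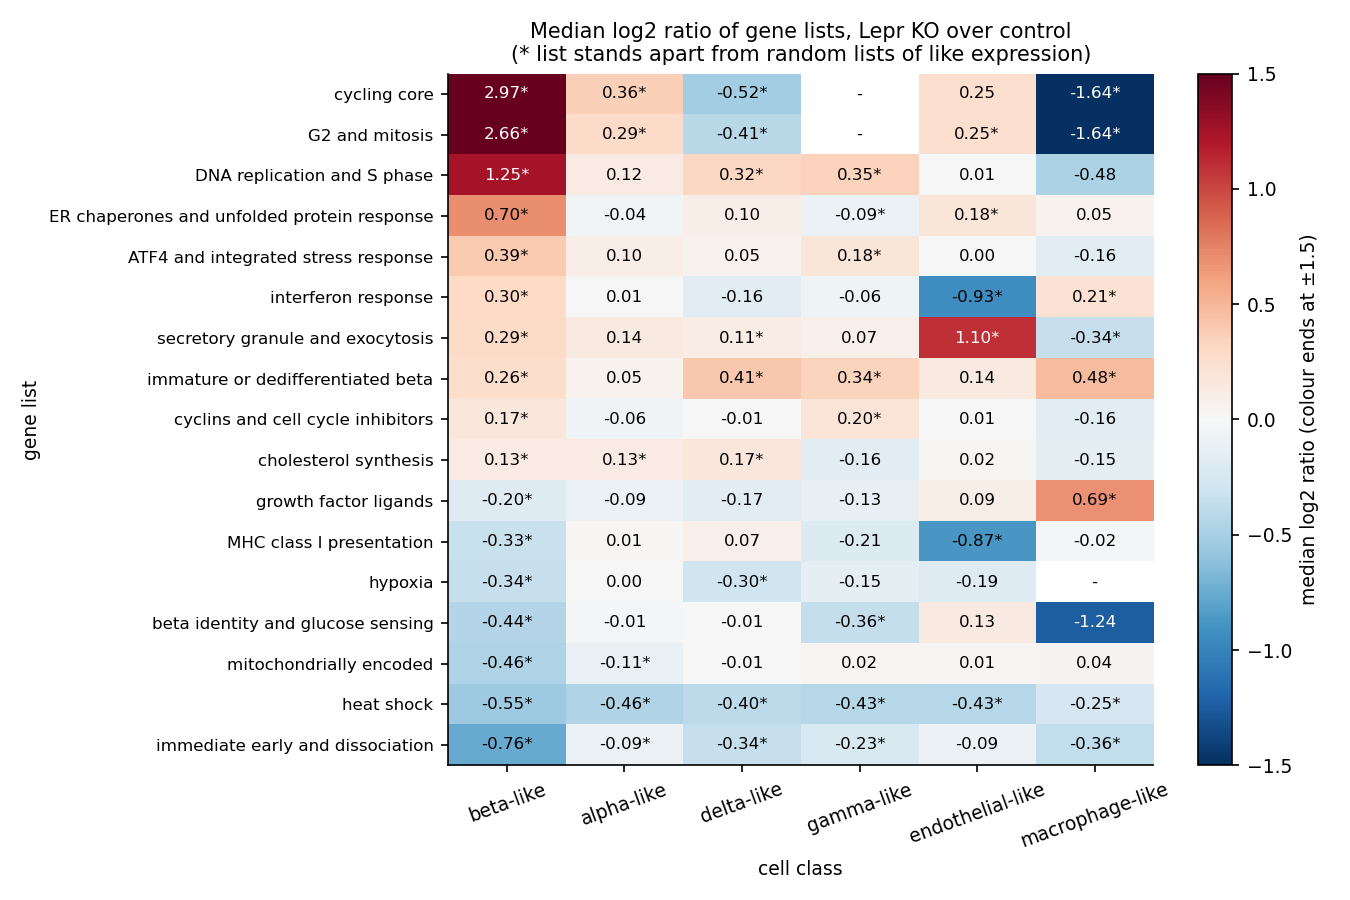
Median log2 ratio, Lepr KO over control (colour and printed value), of each gene list that stood apart in beta-like cells (y axis) in the 6 compared classes (x axis). An asterisk marks a list that stood apart from random lists of like expression in that class, and a dash one with too few measured members. The endoplasmic reticulum chaperone list has 0.70 in beta-like, -0.04 in alpha-like and 0.10 in delta-like cells.

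Markers of other cell types also differed inside the beta-like class. The 8 alpha cell markers together were 2.75-fold higher in the Lepr KO library, at 1352 and 3717 CPM. Most of this was Ttr (829 and 2759 CPM) and Gcg, while Mafb was 1.59-fold lower. Acinar markers stood at 114 CPM in the control and 1.16 in the Lepr KO library, 98.4-fold lower. Erythroid markers stood at 0.749 and 37.6, 50.2-fold higher in the Lepr KO library. Gcg was 1.69-fold and Sst 1.83-fold higher. Free RNA came to 100% and 206% of their levels, but its share was set from these genes and Ppy. Such percentages cannot show whether free RNA accounts for either difference. Among control beta-like cells 1232 had no UMI of an acinar marker. In these and 5799 such Lepr KO cells the endoplasmic reticulum list had a median of 0.58 and Mt1 a log2 ratio of -2.59.

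The heat shock list was also lower in the other endocrine classes of the Lepr KO library, through 5 of 13 genes at 1.5-fold in each and 8 between. It stood apart as lower in endothelial-like (-0.43) and macrophage-like cells (-0.25) too. The endoplasmic reticulum list did not stand apart in alpha-like cells (-0.04) or delta-like cells (0.10, percentile 97.2, just short of the limit). Differences between classes were not tested. In alpha-like cells, 11 genes were at least 2-fold higher (3 to 33 over the alternatives) and 16 at least 2-fold lower (7 to 54) of 5133. The heat shock list had a median of -0.46, with Hspa1b 5.94-fold, Hspa1a 3.85-fold, Dnajb1 3.40-fold and Hsph1 2.12-fold lower. Atf3 (2.53-fold) and Sox4 (2.17-fold) were lower too. Gcg was 1.24-fold higher, Ttr, which carries thyroid hormone and vitamin A, 1.96-fold, Upk3a 1.99-fold, Ssr4 1.72-fold, Pde10a 1.65-fold, Cryba2 1.64-fold and the cold-responsive Rbm3 1.64-fold.

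Several alpha-like lists stood apart by small amounts. CPM without the scaling factor would move the median gene by -0.15 in alpha-like cells and by -0.13 in delta-like and gamma-like cells. Cytosolic ribosomal proteins had a median of 0.23, the nuclear-encoded respiratory chain 0.18, glycolysis 0.15, cholesterol synthesis 0.13 (-0.019 without the scaling factor) and p53 targets 0.19, with Cdkn1a 1.63-fold higher. Glycolysis no longer stood apart in 8 of 17 alternatives, immediate early genes in 7, and cholesterol synthesis in 4 besides its reversal. Ribosome biogenesis had a median of -0.17, immediate early genes -0.09 and mitochondrially encoded genes -0.11. G2 and mitosis genes had a median of 0.29 on few UMIs, with Birc5 at 6 and 23, and free RNA was 28.4% of its level. Erythroid markers in this class stood at 1.01 and 447 CPM (443-fold higher in the Lepr KO library) and acinar markers at 296 and 2.28 CPM (130-fold lower). Insulin transcripts in alpha-like cells were higher in the Lepr KO library (Ins2 2.11-fold), with free RNA at 116% of its level. Ins2 is among the hormones that set the free RNA share of this class, so that percentage cannot show its source.

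In delta-like cells, 9 genes were at least 2-fold higher (6 to 92 over the alternatives) and 28 at least 2-fold lower (10 to 208) of 5024. The genes named by size as lower were Gadd45b 6.24-fold, Hspa1b 5.11-fold, Hspa1a 3.94-fold, Dnajb1 3.55-fold, Cited2 3.29-fold and Hspb1 3.17-fold. The heat shock list had a median of -0.40 with 5 of 13 genes at least 1.5-fold lower, immediate early genes -0.34 and hypoxia -0.30, which did not stand apart in 3 of 17 alternatives. In this class erythroid markers stood at 1.91 and 727 CPM (381-fold higher in the Lepr KO library), while alpha cell markers were 2.18-fold and acinar markers 2.98-fold lower. Sst was 1.30-fold higher. Pdyn, the dynorphin precursor, was 2.20-fold higher, Id2 1.88-fold, Tmed6 1.74-fold, Mest 1.73-fold, Pde10a 1.58-fold and Rbm3 1.57-fold. DNA replication genes had a median of 0.32 on few UMIs (Mcm3, 6 and 27). G2 and mitosis genes had a median of -0.41 and the cycling core -0.52, and both turned positive without doublet removal, with each library clustered alone and with the same weight per cell.

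In gamma-like cells, 15 genes were at least 2-fold higher (3 to 227 over the alternatives) and 25 at least 2-fold lower (9 to 461) of 3718. Scaling without the hormone genes gave 48 and 112. Atf3 (5.02-fold), Hspa1a (4.95-fold), Rgs2 (3.07-fold), Dnajb1 (2.49-fold), Klf9 (2.48-fold) and the glucose-responsive Txnip (2.27-fold) were lower. Gcg was 3.03-fold higher, Ttr 3.40-fold, Gstm5 1.80-fold, Pde10a 1.71-fold, Mrps34 1.70-fold and Chmp3 1.50-fold. Gcg and Ttr are alpha cell markers and make up most of the UMIs of that marker list, which was 3.07-fold higher. Acinar markers were 30.8-fold lower. The class had 380 control and 162 Lepr KO cells, and free RNA was estimated at 31.9% and 28.6% of its UMIs. Its heat shock list had a median of -0.43 and its immediate early list -0.23. Its DNA replication and S phase list stood apart at 0.35, with 4 of 13 genes at least 1.5-fold higher. Its endoplasmic reticulum list had a median of -0.09 with no gene at 1.5-fold, and turned positive under 4 alternatives.

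Endothelial-like cells of the Lepr KO library had lower interferon response and MHC class I genes. Of 6205 genes, 59 were at least 2-fold higher (30 to 517 over the alternatives) and 73 at least 2-fold lower (39 to 346). Of 21 interferon response genes 18 were at least 1.5-fold lower and 1 higher, with a median of -0.93. Ifit3 was 4.75-fold (3.39 to 6.78), Zbp1 4.47-fold and Ifit1 3.79-fold lower, as were the interferon-induced GTPases Igtp (4.39-fold) and Irgm2 (4.24-fold). Of 12 MHC class I genes 9 were lower, with a median of -0.87, and the peptide transporter gene Tap1 was 2.69-fold lower. At 2000 UMIs, 148 of 348 control endothelial-like cells (42.5%, 37.3 to 47.9%) and 65 of 467 Lepr KO cells (13.9%, 10.9 to 17.4%) had at least 5 interferon genes. In macrophage-like cells 35 of 141 control cells (24.8%, 17.9 to 32.8%) and 16 of 81 Lepr KO cells (19.8%, 11.7 to 30.1%) did. In alpha-like cells 0 of 1585 and 0 of 1177 did, and the median depths of endothelial-like cells were 4988.5 and 4394.5 UMIs.

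Igfbp5, which binds insulin-like growth factors, was 6.63-fold lower in Lepr KO endothelial-like cells, and Igf1 2.37-fold lower. Kcne3, a potassium channel subunit, was 4.66-fold higher, the urokinase receptor Plaur 2.62-fold, Maf 2.34-fold, Prss23 2.24-fold, Pdlim1 2.24-fold and Phlda3 2.11-fold. Secretory granule genes had a median of 1.10, but these are endocrine transcripts. Free RNA was 80.1% of the level of Iapp, which is itself among the hormones that set the free RNA share. Ppy was 11.2-fold lower, and it too is not an endothelial gene. Delta cell markers together were 7.39-fold and erythroid markers 2.16-fold higher, and acinar markers 26.8-fold lower. The heat shock list had a median of -0.43, while the immediate early list (-0.09) did not stand apart. The endoplasmic reticulum list had a median of 0.18 and stood apart, with 4 of 23 genes at least 1.5-fold higher and none lower. Sdf2l1 was 2.60-fold higher, with free RNA at 53.5% of its level, and beta cell markers were 2.36-fold higher in this class. The median was -0.00090 with no doublets removed, and the list no longer stood apart in 4 further alternatives of 16.

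Lepr (ENSMUSG00000057722) was detected almost only in endothelial-like cells. It had 73 UMIs in 390 control cells, a level of 29.4 CPM before scaling. In 504 Lepr KO cells it had 43 UMIs, a level of 15.3. It was 1.85-fold lower in the Lepr KO library (1.25 to 2.77). Beta-like cells had 0 UMIs among 3843 control cells and 1 among 5944 Lepr KO cells, and alpha-like and delta-like cells had none. The labels do not say which exons were removed. Transcript tags were read at the 3' end, so remaining UMIs do not show how many alleles were left intact.

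Macrophage-like cells were few, 160 and 100, with 665891 and 267705 UMIs, and counting error was wide. Free RNA was estimated at 21.1% of the control and 6.24% of the Lepr KO UMIs, and alpha, delta and gamma cell markers were 7.11-fold, 7.03-fold and 11.1-fold lower. Ccl5 was 2.66-fold higher in the Lepr KO library (2.21 to 3.20), the galectin gene Lgals3 1.92-fold, Prdx1 1.80-fold, Apobec1 1.80-fold, Ccl3 1.51-fold and Fxyd5 1.49-fold. Cxcl2, a neutrophil attractant, was 2.88-fold lower (2.27 to 3.69), Dusp2 2.96-fold, Hist1h2ae 2.86-fold, Stmn1 2.75-fold and S100a10 2.45-fold. The inflammatory macrophage list had a median of -0.56 with members in both directions, Cxcl10 4.56-fold higher and Ccl2 4.12-fold lower on 21 and 2 UMIs. Sst was 7.23-fold lower and is not a macrophage gene. The heat shock list had a median of -0.25, the immediate early list -0.36 and lysosome genes 0.24. Lysosome genes no longer stood apart in 5 of 13 alternatives. Interferon response genes stood apart as higher, at 0.21. They no longer did in 8 of 13 alternatives and reversed in 1.

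Genes that were 2-fold apart in beta-like cells were compared with the same genes in the other classes, macrophage-like cells left out for their counting error. Of 35 such genes higher in Lepr KO beta-like cells and measured in alpha-like cells, 9 were at least 1.5-fold higher there and none 1.5-fold lower, against 0.774% of all genes measured in both. Of 23 lower in beta-like cells, 7 were at least 1.5-fold lower in alpha-like cells, against 0.633%. In delta-like cells 7 of 41 were higher too and 2 lower, while 11 of 25 were lower too, against 0.488% and 1.01% of all genes. In gamma-like cells 11 of 35 were higher too and 18 of 28 lower too, against 1.14% and 2.79%, with none opposite. In endothelial-like cells 11 of 34 were higher too and 1 lower, and 7 of 22 were lower too, against 2.71% and 1.12%. This sharing can include free RNA of beta cells, since beta cell markers were 2.17-fold higher in Lepr KO alpha-like cells (13116 and 28443 CPM).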

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

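The 3 patterns weighed here were chosen after the leading genes of the clusters had been seen, and the limits of each test were written before its value was computed.

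In 8 cases a gene list stood apart in beta-like cells in 1 direction and in another class in the other direction. With 1 library per group, none of these differences between classes was tested. Interferon response genes had a median log2 ratio of 0.30 in beta-like cells and -0.93 in endothelial-like cells. The endoplasmic reticulum chaperone list had 0.70 in beta-like cells and -0.090 in gamma-like cells, where 4 alternatives gave a positive median. Secretory granule genes had 0.29 in beta-like cells and -0.34 in macrophage-like cells, where they are foreign transcripts and 5 alternatives gave a positive median (0.34 to 1.69). Growth factor ligands had -0.20 in beta-like cells and 0.69 over 3 members in macrophage-like cells, where the median was -0.20 with no filter on low counts. G2 and mitosis genes had 2.66 in beta-like cells, -0.41 in delta-like cells and -1.64 in macrophage-like cells. The cycling core, whose genes are all in the G2 and mitosis list, had 2.97, -0.52 and -1.64 in the same classes, on few UMIs in the last 2. In delta-like cells both lists turned positive under 3 alternatives.

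Barcodes with under 500 detected genes, which were left out of the cells and used only for the free RNA profile, also differed between the libraries. Erythroid markers were 3.44-fold higher in the Lepr KO library, at 30639 against 8900 CPM. Delta markers were 2.96-fold higher, at 4173 against 1408. No biological explanation was tested for these 2 values.

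The first pattern weighed is the higher cycling share of beta-like cells in the Lepr KO library. Deeper sequencing is not enough for it, since the ratio of shares was 18.3 with every cell thinned to 1 depth, with a lower counting limit of 11.6. Free RNA from cycling cells would reach other cells too, but 0.340% of Lepr KO alpha-like cells were cycling (upper limit 0.868%), against 6.93% of beta-like cells at the same depth. Alpha-like cells are a weak check, since free RNA was estimated at 5.20% of their UMIs and 18.8% of those of beta-like cells. Delta-like cells, at 13.4% free RNA, had 0.189% cycling (upper limit 1.05%). Endothelial-like cells, at 15.5%, had 1.71% (upper limit 3.35%). A difference in all cells of the library would show in other classes, whose ratio was 1.09 (upper limit 2.26), against 24.2 in beta-like cells. A difference tied to the genotype, which here covers Cre as well as Lepr, stays a hypothesis. It cannot be separated from a difference between 2 single preparations.

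The second pattern is the higher endoplasmic reticulum chaperone list in Lepr KO beta-like cells, whose median of 0.67 to 0.71 under the scalings run argues against scaling. The medians in alpha-like cells (-0.04) and delta-like cells (0.10) lay at least 0.61 below the 0.70 of beta-like cells, which argues against a difference of this size in all cells. Endothelial-like cells share it in part, with a median of 0.18 that stood apart in 11 of 16 alternatives and was -0.00090 with no doublets removed, in a class where beta cell markers were 2.36-fold higher. Without cells that had a UMI of a cycling core gene, 102% of the median remained (0.72), so cycling cells do not account for it. A difference tied to the genotype stays open as a hypothesis, as does one between preparations.

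The third pattern is the higher Mt1 level in control beta-like cells. Acinar RNA is a poor explanation, since beta-like cells with no UMI of an acinar marker kept 95.8% of the log2 ratio (-2.59). A library-wide difference and one of beta-like cells cannot be told apart. Mt1 was 1.05-fold higher in control alpha-like, 1.86-fold in delta-like and 3.39-fold in endothelial-like cells, so other classes share it in part. In gamma-like and macrophage-like cells it was 1.57-fold and 1.24-fold higher in the control. Handling and genotype both stay open, and neither was tested.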

How the results depend on the processing

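The alternatives without cells that had a UMI of a cycling core gene or of an acinar marker were chosen after the data were seen, and the others before. The cause of a difference under an alternative was not tested, except that a looser or stricter filter on counts takes in more or fewer genes.

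The 34 lists in beta-like cells gave 575 values. Of these, 542 kept their side of the limits for standing apart, 14 no longer stood apart and 19 came to stand apart. The sign changed in 20, all in lists that did not stand apart, and so 0 values are called reversed. The endoplasmic reticulum list ranged from 0.58 to 0.76, beta identity from -0.48 to -0.36 and G2 and mitosis from 1.35 to 3.60. The 90 named genes in beta-like cells gave 1527 values. In 15 the sign changed or the ratio came to 0, and 5 of these are called reversed because the interval of the fold left out 1. Mt1 ranged from -2.82 to -2.59 and Fkbp11 from 2.19 to 2.31. In other classes 10 of 1438 gene values did not keep their sign, 4 of them reversed in this sense. Of 783 values of lists that stood apart there, 31 reversed and 109 no longer stood apart.

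Beta-like shares were 68.3% in the Lepr KO library with at least 2000 UMIs per cell, 48.7% and 64.6% with a mitochondrial limit of 25%, 47.3% and 63.8% with no doublets removed, and 64.9% in the Lepr KO library with each library clustered alone. Cycling shares of Lepr KO beta-like cells were 12.01% with at least 2 core genes, 9.35% with 5 and 12.5% with no thinning, and the ratio ranged from 11.9 to 21.8.

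In beta-like cells the immature list had 0.11 with a mitochondrial limit of 25%, 0.11 with no doublets removed, 0.0084 with each library clustered alone and 0.13 without acinar-UMI cells, and no longer stood apart. With free RNA subtracted, cyclins (0.065), cholesterol synthesis (0.086) and growth factor ligands (-0.10) no longer stood apart, and Atf3 reversed (0.033). Hypoxia had -0.17 with a pseudocount of 5 and -0.087 with no filter on low counts, where growth factor ligands had -0.011. Without cycling-UMI cells, cyclins had 0.0018, and Sst (-0.027) and Ezh2 (-0.021) reversed. Without acinar-UMI cells, granule genes (0.27), MHC class I (-0.34) and growth factor ligands (-0.19) no longer stood apart, on 1232 control cells. Carbohydrate response came to stand apart as lower in 5 of 17 alternatives (lowest -0.33) and extracellular matrix in 6 (lowest -0.52). Resident and inflammatory macrophage genes did in 2 each, as did ribosomal proteins as higher, and genes kept low (-0.16) and ribosome biogenesis (0.12) in 1 each. Higd1a reversed with no doublets removed (-0.012) and Sst with each library clustered alone (-1.69).

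In delta-like cells, G2 and mitosis and the cycling core reversed with no doublets removed (0.52 and 0.54), with each library clustered alone (2.18 and 2.33) and with the same weight per cell (0.72 and 0.76). Without the scaling factor, granule genes (-0.018) and the respiratory chain (-0.029) reversed in delta-like cells and cholesterol synthesis (-0.019) in alpha-like cells. In gamma-like cells, the ATF4 list reversed with mitochondrial limits of 10% (-0.12) and 25% (-0.059), at a clustering resolution of 2 (-0.077) and with cells thinned to 1 depth (-0.12). The endoplasmic reticulum list reversed there with at least 2000 UMIs (0.053), a limit of 25% (0.061), each library clustered alone (0.087) and a resolution of 2 (0.050). Beta identity (0.088, free RNA subtracted), cyclins (-0.00074, no filter) and glycolysis (-0.010, same weight per cell) reversed there too. In endothelial-like cells, Ube2c (0.10) and the endoplasmic reticulum list (-0.00090) reversed with no doublets removed, and Ifi27l2a (-0.51) and G2 and mitosis (-0.034) with each library clustered alone.

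In macrophage-like cells, secretory granule genes reversed with a mitochondrial limit of 25% (1.69), no doublets removed (0.34), free RNA subtracted (1.50), the same weight per cell (0.50) and thinning to 1 depth (0.46). Interferon genes reversed with a limit of 25% (-0.21), and the immature list with no doublets removed (-0.14) and with no filter on low counts (-0.78), where growth factor ligands had -0.20. S100a10 reversed without cycling-UMI cells (0.42) and Sst without acinar-UMI cells (1.20), the latter on 58 control and 97 Lepr KO cells. With each library clustered alone, no Lepr KO cluster was named macrophage-like.

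Counts of genes at least 2-fold apart depended on the filter on counts, the scaling and other settings. With no filter the genes higher and lower in the Lepr KO library were 289 and 113 in beta-like, 33 and 54 in alpha-like, 92 and 208 in delta-like, 517 and 346 in endothelial-like and 227 and 461 in gamma-like cells. With at least 50 CPM they were 23 and 17 in beta-like, 7 and 8 in alpha-like, 30 and 39 in endothelial-like and 5 and 9 in gamma-like cells, with 10 lower in delta-like cells. Without hormone genes in the scaling they were 124 and 116 in beta-like and 48 and 112 in gamma-like cells, and with CPM of all UMIs 38 were lower in gamma-like cells.

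With free RNA subtracted the counts were 3 and 7 in alpha-like and 23 and 39 in gamma-like cells. With cells thinned to 1 depth they were 122 and 164 in endothelial-like and 35 and 110 in gamma-like cells, with 17 higher in delta-like cells. In gamma-like cells 6 were higher with at least 2000 UMIs, 6 with a limit of 25%, 3 with no doublets removed, 4 at a clustering resolution of 2 and 8 with a pseudocount of 5, and 38 were lower with the same weight per cell. With no doublets removed 38 were higher in endothelial-like cells, at a resolution of 2 there were 20 higher in alpha-like cells, and with each library clustered alone 25 higher in delta-like cells. Without cycling-UMI cells 7 were higher in alpha-like cells. Without acinar-UMI cells 56 were lower in beta-like, 9 lower in alpha-like, 59 higher and 113 lower in delta-like, 97 higher in endothelial-like and 45 lower in gamma-like cells.

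Depth limits the small classes most. Macrophage-like cells held 267705 UMIs in the Lepr KO library, against 182670055 in beta-like cells, and in a simulation with no true difference 496 of 4923 genes reached 2-fold there.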

Other observations

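Inside the Lepr KO library, 743 cycling beta-like cells were set beside the 4294 with no UMI of a cycling core gene. The list of beta cell identity and glucose sensing had a median log2 ratio of -0.32 in cycling cells, and secretory granule genes had -0.20. Mitochondrially encoded genes had -0.38, with 13 of 13 lower, carbohydrate response genes -0.29, fatty acid synthesis -0.20 and lysosome genes -0.15. Higher in cycling cells were resident macrophage genes (0.67, with 5 of 8 at 1.5-fold), cyclins and inhibitors (0.31), the immature list (0.18), the respiratory chain (0.15) and the 3 cell cycle lists. Slc2a2 (-0.74), Mafa (-0.39), Ucn3 (-0.34) and Fkbp11 (-0.41) were lower in cycling cells, while the cell cycle inhibitor Cdkn1a (1.15) and Mt1 (0.66) were higher. Pdx1 (0.03) was close, and the endoplasmic reticulum list (-0.03) did not stand apart. Cycling cells were picked by their UMIs of cycling core genes, all of which are also in the G2 and mitosis list. The higher levels of these lists therefore follow from the choice of cells and are not a finding. Deeper cells are favoured too, and no test was made.

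Some clusters of other classes were also unequal. Alpha-like cluster 13, led by Gcg, Dbpht2 and Mafb, held 379 control cells and 0 Lepr KO cells. Cluster 11, with Atf3 among its leading genes, held 393 and 95, while cluster 3 held 837 and 1092. Unnamed cluster 20, led by Sst and Ly6h, held 20 control and 103 Lepr KO cells. It detected 10 of 12 beta cell markers at a median of 33228 UMIs, against 7160 in delta-like cluster 6. It cannot be read as delta-like cells alone.

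Xist, which is expressed from the inactive X chromosome, was present in both libraries, at 409 and 290 CPM in beta-like cells. The Y-linked gene Uty had 1 and 3 UMIs there, and Ddx3y and Eif2s3y had 0. In the left-out barcodes, acinar markers stood at 28072 CPM in the control and 22.0 in the Lepr KO library.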
